A study of Homo sapiens with 6 samples.

How the data were processed

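The series holds 6 arrays, 3 of HEK293 cells transfected with a plasmid for human SNRK fused to GFP and 3 of cells transfected with the GFP plasmid, and per the labels total RNA was taken after 48 h, amplified to biotin-labelled cRNA and hybridised to Illumina expression arrays. The groups and replicate numbers come from the sample labels. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The authors deposited a table with 1 intensity per probe and array on a linear scale, neither normalized between arrays nor background-subtracted, to judge from the values. Beside each intensity, the deposited table gives a detection p-value, per the file headers. The authors also deposited normalized intensity values, as whole numbers on a linear scale, for the same arrays. The submitters' processing notes name lumi for these, with no version, and the steps and the transformation behind them are not given in the sources used here. The median of the authors' normalized values was 170 on each array, and the scale between these values and the unnormalized ones stays unknown. Across the tested probes, differences between arrays in the authors' normalized values correlated at 0.840 to 0.877 with those in the values normalized as described below. With those in the unnormalized intensities they correlated at 0.983 to 0.995, across 7578 probes with a signal above 256. These 2 ranges differ in both the probes and the processing. The scanner, its software and the slide of each array are not given in the sources used here. All columns of both tables belonged to a sample of the series.

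Signals were background-corrected with limma's neqc, in which the mean and SD of the negative controls were inferred from the detection p-values, because no control rows are in the table. An offset of 16 was added, and the values were quantile normalized and taken to log2. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 18046 of 48701. For each probe a linear model with a group term was fitted with limma's lmFit and moderated with eBayes without trend or robust options (4 residual and 4.38 prior degrees of freedom), and p-values, all two-sided, were adjusted by Benjamini-Hochberg over all 18046 probes. At an unadjusted p of 0.05, 4728 probes passed. A log2 difference is SNRK minus GFP throughout, a standard error is the moderated one of the fit, and a fold is 2 to the power of the size of the difference. Where a probe was undetected on all arrays of 1 group, the fold is a bound: the mean log2 value of the detected group was set against the mean of, per array, the higher of the lowest detected signal and the probe's own value, on normalized log2 values. The size of a difference depends on the background correction: the log2 difference of SNRK was 0.44 with it and 0.34 without it. Replicate arrays shared at most 1 identical signal across the 48701 probes, and each was counted as a sample.

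Gene names are those of the array table, which can be old. They were matched to the symbols and synonyms of human RefSeq genes of the assembly GRCh38.p14, used for names and gene lengths only. Of the 48701 probes 18786 carried a current symbol, 3965 a synonym that was updated, 1084 a symbol without a match, 24832 a locus or cluster number and 34 a symbol turned into a date by spreadsheet software. Among the tested probes these numbers were 11368, 2518, 479, 3657 and 24. Probe sequences and positions were not used here, so no coordinates are given and cross-hybridisation, GC content and the place of a probe in its transcript could not be examined. For the count of genes and the gene lists, each gene was represented by the tested probe with the highest mean signal, and the text says where other probes of a named gene differed.

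The following choices were fixed before the data were examined: the test, the filter, the alternatives, 32 gene lists and the rule for named genes. The named genes are SNRK, CACYBP, CTNNB1 and MYC; the 12 largest rises and the 12 largest falls among probes with 1 gene symbol that passed an adjusted p of 0.05 and whose SNRK arrays all lay above or all below the GFP arrays, with each gene represented by its tested probe of the highest mean signal, so that a larger change on a dimmer probe was not taken; and up to 4 members with the smallest p in each list that passed or held a member that passed. Symbols that are locus or cluster numbers were counted and not named, and 1 gene that the rule took is not reported here. The lists cover Wnt and beta-catenin signalling, AMPK-related kinases, metabolism, stress responses, cell cycle and death, histones, general cellular genes and markers of other cell types. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists, and again with an estimated correlation. Counts of members are given over all tested probes and adjusted over the list alone. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used. SNRK was also compared with an exact permutation test of the 3 against 3 arrays.

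The procedure was tested on simulated data for the comparison of SNRK against GFP, with 18046 probes of which 200 were changed. It recovered 47.8% of probes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2, and 4 of 166 calls were false. In the simulated test of 31 lists, the shifted list had an adjusted p of 2.48e-18 by camera with Benjamini-Hochberg and 0 other lists passed. The simulated noise was drawn independently for each probe and array, without differences that many probes of an array share. These rates therefore check the procedure and do not give the share of false calls on the real arrays. The alternatives tried were quantile normalization without background correction, median scaling, the authors' normalized values, other filters, moderation with trend and robust options, array quality weights, the replicate number as a block, other thresholds, other forms of the list test and leaving out each array in turn. Added after the data were seen were a fit without the replicates numbered 3, scaling to the median of the filtered probes, and a fit without probes named only by a cluster or locus number.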

Results

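Gene expression was measured in HEK293 cells, a human embryonic kidney line, 48 h after transfection with a plasmid encoding human SNRK fused to GFP or with the plasmid encoding GFP alone. SNRK is a serine/threonine kinase related to AMP-activated protein kinase (AMPK). Each group held 3 Illumina bead arrays, and the number of arrays limits the precision of every value. Each array carried the same 48701 probes. Detection p lay below 0.05 for 17517 to 17717 probes on the GFP arrays and for 18138 to 18212 probes on the SNRK arrays, or 36.0% to 37.4% of the probes. The median signal was 100.4, 94.4 and 93.8 on GFP replicates 1 to 3 and 101.7, 102.0 and 96.1 on SNRK replicates 1 to 3. After the filter on detection 18046 probes were tested, of which 14365 carried a gene symbol and represented 12262 genes. Correlations across these probes ranged from 0.991 to 0.996 within the groups and from 0.980 to 0.992 between them. The first principal component held 58.0% of the variance and separated the groups, with GFP replicate 3 at -10.7 and SNRK replicate 3 at 10.2 lying nearest to the other group. The remaining GFP arrays lay at -26.3 and -22.1, and the remaining SNRK arrays at 19.6 and 29.2.

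The first question was whether the SNRK transcript itself differed between the groups. SNRK was 1.35-fold higher in cells given the SNRK-GFP plasmid, at a log2 signal of 8.62 ± 0.06 (SD, n = 3) against 8.19 ± 0.11 in the GFP group. The log2 difference was 0.44 with a standard error of 0.09 (limma, Benjamini-Hochberg adjusted p = 0.0322), and each SNRK array lay above each GFP array. Before normalization the signals were 485.5, 460.2 and 457.9 on the SNRK arrays and 349.9, 381.7 and 371.9 on the GFP arrays. An exact two-sided permutation test of the 3 against 3 arrays gave p = 0.1, the smallest that its 20 splits allow. SNRK had 1 probe, whose position was not used here, so that whether it lies within the transfected coding sequence is unknown and the value does not check the labels. Without GFP replicate 1, GFP replicate 2, SNRK replicate 1 or SNRK replicate 2 the difference no longer passed the threshold, with limma Benjamini-Hochberg adjusted p of 0.128, 0.109, 0.112 and 0.0605, and scaling to the median of the filtered probes, tried only after the data were seen, gave 0.38 with an adjusted p of 0.0505. In the authors' normalized values the SNRK difference was 0.29 and passed (limma, Benjamini-Hochberg adjusted p = 0.0131).

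CACYBP, CTNNB1 and MYC were examined next, as genes of beta-catenin turnover and signalling. CACYBP, which encodes a component of a ubiquitin ligase complex that acts on beta-catenin, rose 1.66-fold (log2 0.73, standard error 0.10, limma with Benjamini-Hochberg adjusted p = 0.00686). Its log2 signal was 11.09 ± 0.13 in the SNRK group and 10.35 ± 0.04 in the GFP group (SD, n = 3). This call held without each of the 6 arrays in turn, with a highest adjusted p of 0.0398 by limma with Benjamini-Hochberg. A second, dimmer CACYBP probe gave a log2 difference of -0.12 (limma, Benjamini-Hochberg adjusted p = 0.610). CTNNB1, which encodes beta-catenin, did not pass, with a log2 difference of 0.26, a standard error of 0.17 and an adjusted p of 0.367 by limma with Benjamini-Hochberg. The CTNNB1 difference was 0.09 without SNRK replicate 2 and 0.45 without SNRK replicate 3, and did not pass in either fit. MYC, a target of beta-catenin signalling, did not pass either, with a log2 difference of -0.35, a standard error of 0.14 and an adjusted p of 0.155 by the same test. Without SNRK replicate 3, however, MYC lay at -0.50 and passed (limma, Benjamini-Hochberg adjusted p = 0.0342), as it did with array quality weights (-0.45, adjusted p = 0.0388) and without both replicates numbered 3 (-0.55, adjusted p = 0.0378).

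The main comparison asked which transcripts differed between cells with SNRK-GFP and cells with GFP. In all, 1480 of 18046 probes passed a limma Benjamini-Hochberg adjusted p of 0.05, of which 794 rose and 686 fell in the SNRK group. With 1 probe per gene, 608 genes rose and 453 fell among 12262, so that 8.65% of the genes passed. At least 1.5-fold rises and falls numbered 367 and 401 probes, at least 2-fold ones 52 and 100, and at least 4-fold ones 1 and 18. Probes named only by a transcript cluster number fell more often than they rose, with 165 falls and 37 rises among 2151, against 477 falls and 700 rises among 14365 probes with a gene symbol. The odds ratio of a fall over a rise was 6.55 (95% confidence interval 4.46 to 9.81, Fisher's exact test p = 2.05e-28, with probes as the units, which are not independent replicates). Among the 18 probes with a log2 fall beyond 2, 10 were named by a cluster number, 3 by a locus number and 5 by a gene symbol. GFP replicate 3 lay on the SNRK side of the mean of the other GFP arrays for 82.1% of the 1480 probes that passed, and for 55.3% of the 8397 probes with an adjusted p of 0.5 or more by limma with Benjamini-Hochberg. SNRK replicate 3 lay on the GFP side of the mean of the other SNRK arrays for 68.4% and 55.2% of the same probes.

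The number of probes that passed depended on single arrays. It was 75 rises and 134 falls without GFP replicate 1, 71 and 133 without GFP replicate 2, 103 and 159 without SNRK replicate 1, and 307 and 411 without SNRK replicate 2. Without both replicates numbered 3, an alternative added after the data were seen, 1075 probes rose and 931 fell. Of the 1636 genes with several tested probes, 236 had a probe that passed, and in 138 of these (58.5%, exact 95% confidence interval 51.9 to 64.8) the brightest other probe of the gene went the same way as the probe with the smallest p.

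**Figure D1:**
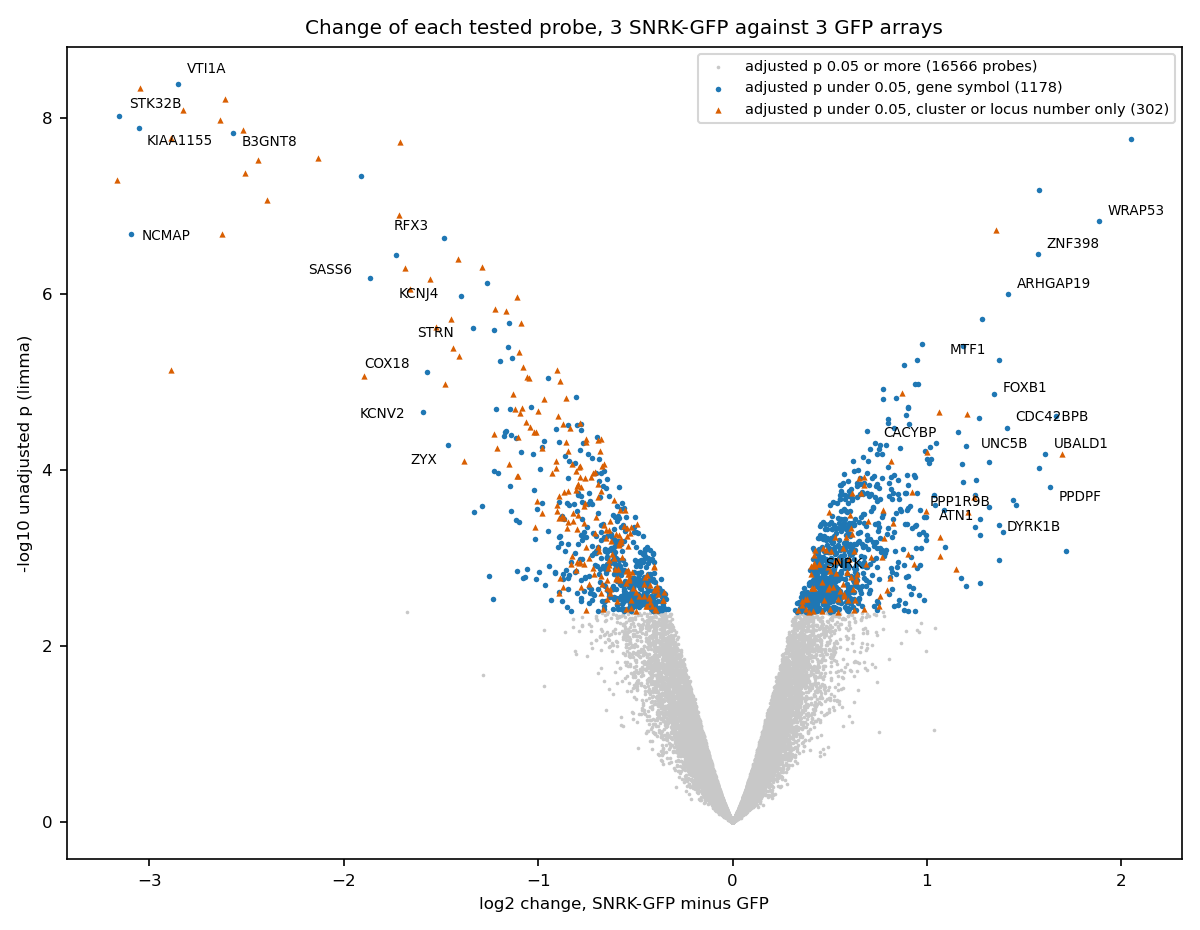
Each point is 1 of 18046 tested probes, with the log2 change (SNRK-GFP minus GFP) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; colours separate probes past an adjusted p of 0.05 with a gene symbol, those with only a cluster or locus number, and all others. The 18 steepest falls lie beyond a log2 change of -2, and 1 rise lies beyond a log2 change of 2.

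With each gene represented by its brightest tested probe, the largest falls were those of STK32B, NCMAP and KIAA1155. STK32B, which encodes a serine/threonine kinase, was 8.91-fold lower in the SNRK group (log2 -3.16, standard error 0.14, limma with Benjamini-Hochberg adjusted p = 2.83e-05). NCMAP, named for a protein of noncompact myelin and listed on the array as C1ORF130, was 8.54-fold lower (log2 -3.09, standard error 0.20, limma with Benjamini-Hochberg adjusted p = 0.000157). KIAA1155 fell by 3.05 on the log2 scale, with a standard error of 0.14. VTI1A, a SNARE protein of vesicle traffic, and B3GNT8, a glycosyltransferase, were 7.22-fold and 5.94-fold lower. SASS6, which encodes a protein needed for centriole assembly, was detected on all 3 GFP arrays and on 0 of 3 SNRK arrays, and was at least 3.00-fold lower in the values normalized here. The potassium channel genes KCNV2 and KCNJ4 were 3.02-fold and 2.63-fold lower, although a dimmer KCNJ4 probe gave a log2 difference of -0.07. RFX3, a transcription factor of ciliated cells, was 2.80-fold lower on its brightest probe, while its 2 dimmer probes gave log2 differences of -0.30 and -0.33 that did not pass. COX18, a mitochondrial membrane protein of cytochrome oxidase assembly, was 2.97-fold lower and was detected on 1 of 3 SNRK arrays. ZYX, which encodes the focal adhesion protein zyxin, and STRN, which encodes the phosphatase scaffold striatin, were 2.76-fold and 2.52-fold lower. All 12 of these falls passed without each of the 6 arrays in turn and in the authors' normalized values. Their size depended on the processing: the median log2 difference of the 12 was -1.73 here, -1.28 without background correction and -1.10 in the authors' normalized values, where STK32B lay at -1.47, NCMAP at -2.45, KIAA1155 at -1.81, VTI1A at -1.62, B3GNT8 at -1.13, KCNV2 at -0.79, KCNJ4 at -0.71, SASS6 at -0.41 and COX18 at -0.34. The bound on the fall of SASS6 holds for the values normalized here alone, and SASS6 and COX18 lay at -0.71 and -0.59 without background correction. STK32B, NCMAP, KIAA1155, VTI1A and B3GNT8 were the 5 gene symbols among the 18 probes with a log2 fall beyond 2. Those 18 shared a profile across the arrays, and a shared source of signal behind them stays open. Passing again without an array does not separate such a source from lower transcript levels of these 5 genes.

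Among the same brightest probes, WRAP53, PPDPF and UBALD1 had the largest rises. WRAP53, which encodes a telomerase and Cajal body protein and is listed on the array as WDR79, was 3.69-fold higher (log2 1.88, standard error 0.12, limma with Benjamini-Hochberg adjusted p = 0.000128). PPDPF, listed as C20ORF149, and UBALD1, listed as FAM100A, were 3.10-fold and 3.05-fold higher. ZNF398, a zinc finger protein, was detected on 0 of 3 GFP arrays and on all 3 SNRK arrays, and was at least 2.65-fold higher in the values normalized here. PPP1R9B, which encodes the actin-binding protein spinophilin, was 2.72-fold higher, ARHGAP19, which encodes a GTPase-activating protein, 2.67-fold, and CDC42BPB, a kinase that binds CDC42, 2.66-fold. MTF1, the metal-responsive transcription factor, was 2.59-fold higher and the kinase gene DYRK1B 2.58-fold. FOXB1, a forkhead transcription factor gene, was 2.54-fold higher and was detected on 1 of 3 GFP arrays. UNC5B, a netrin receptor, and ATN1, which encodes atrophin, were both 2.50-fold higher. Without 1 array, 4 of these 12 rises no longer passed: ATN1, DYRK1B and PPP1R9B without GFP replicate 1, GFP replicate 2 or SNRK replicate 1, and PPDPF without GFP replicate 2 or SNRK replicate 1. The highest adjusted p by limma with Benjamini-Hochberg was then 0.0706 for ATN1, 0.0803 for DYRK1B, 0.0649 for PPP1R9B and 0.0565 for PPDPF. The median log2 difference of the 12 rises was 1.42 here, 1.06 without background correction and 0.87 in the authors' normalized values, where all 12 passed. WRAP53 lay there at 0.62, PPDPF at 1.11, UBALD1 at 1.20, CDC42BPB at 0.87, ATN1 at 0.86, PPP1R9B at 0.57, UNC5B at 0.51, ZNF398 at 0.33 and FOXB1 at 0.28. The bound on the rise of ZNF398 likewise holds for the values normalized here alone, and ZNF398 and FOXB1 lay at 0.58 and 0.50 without background correction.

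**Figure D2:**
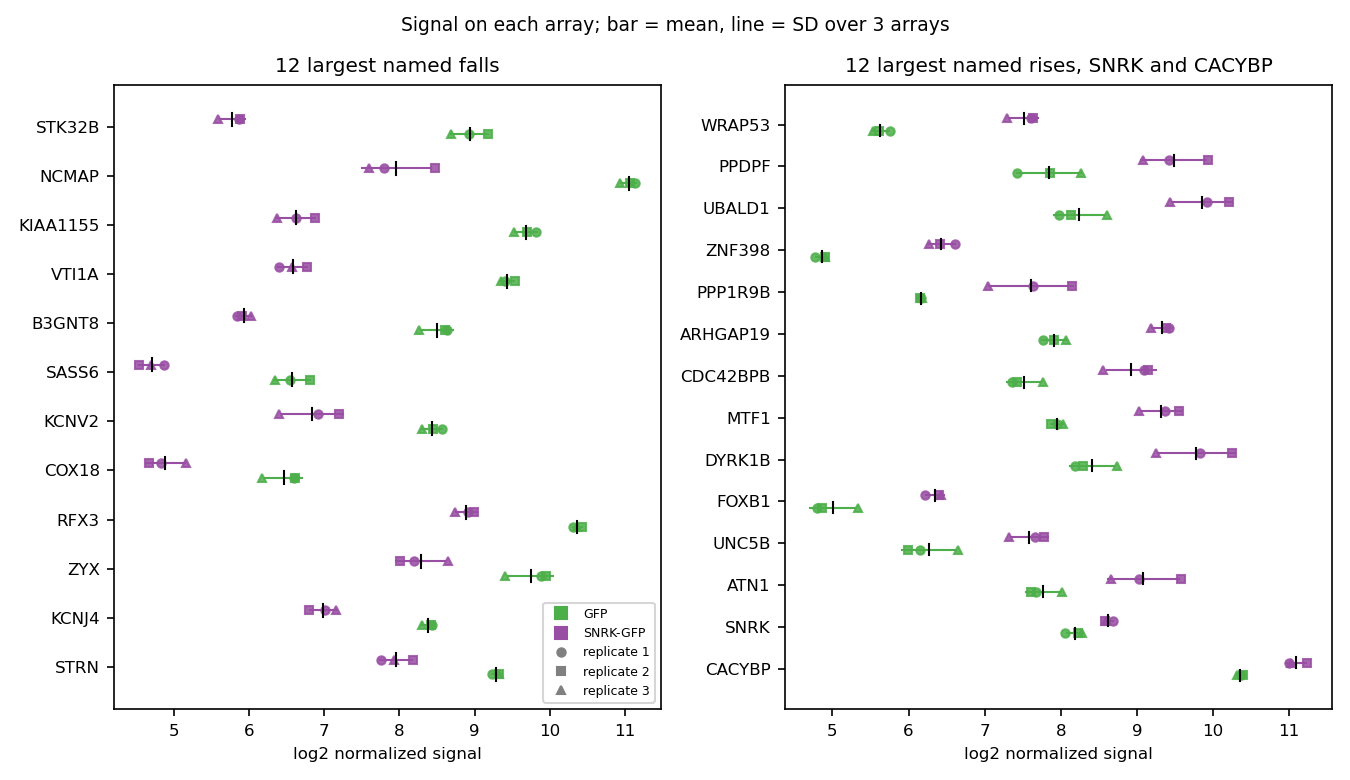
Log2 normalized signal on each of the 6 arrays for the 12 largest falls and the 12 largest rises among the brightest probes of genes with a symbol, and for SNRK and CACYBP; colours separate the groups, symbols the replicates, bars are means and lines are SD over 3 arrays. The GFP and SNRK arrays do not overlap for any of these genes, which the naming rule required of the falls and rises.

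Of 32 gene lists, 31 had at least 5 measured members and 1 passed, the list of amino acid response genes, the targets of the transcription factor ATF4 (camera with preset correlation, Benjamini-Hochberg adjusted p = 0.000293; adjusted p = 0.215 with an estimated correlation). Of its 34 measured members 6 fell, 1 rose and 27 did not pass, with a median log2 difference of -0.21; adjusted over the list alone, 9 fell and 1 rose. SLC7A5 and SLC3A2, the subunits of a large neutral amino acid transporter, were 1.67-fold and 1.47-fold lower, and a second SLC3A2 probe gave a log2 difference of -0.33 (limma, Benjamini-Hochberg adjusted p = 0.0955). ATF5 and NUPR1, which encode stress-induced transcriptional regulators, fell by 0.68 and 0.58 on the log2 scale. SESN2, which encodes a stress-induced inhibitor of TORC1, was the member that rose, by 1.54-fold. In the authors' normalized values NUPR1 lay at -0.33 and SESN2 at 0.41. At an unadjusted camera p of 0.05, 4 lists passed, and 2 did with an estimated correlation; after adjustment 0 lists passed with an estimated correlation. Of the 67 named list members that passed, CACYBP and FOXM1 did so without each of the 6 arrays in turn. The other 65 did not pass without at least 1 array: 64 were lost without GFP replicate 1, 64 without GFP replicate 2, 62 without SNRK replicate 1, 44 without SNRK replicate 2, 18 without GFP replicate 3 and 9 without SNRK replicate 3. In the authors' normalized values 62 of the 67 passed, all but BCL3, FOSB, IRF1, NFKB2 and PFKFB2, and the log2 differences of 33 of the 67 were over 1.5 times smaller there. Scaling to the array median ended the calls of BTG2, FDXR, ISG20, NDUFA13 and SOX9, and without the filter on detection 40 of 91 named genes no longer passed.

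The Wnt and beta-catenin target list did not pass (camera, Benjamini-Hochberg adjusted p = 0.190), and of 25 measured members 4 rose and 1 fell; adjusted over the list alone, 7 rose and 1 fell. TCF7L2, a transcription factor that binds beta-catenin, was 2.39-fold higher, and PPARD, TWIST1 and SOX9 were 1.92-fold, 1.60-fold and 1.29-fold higher, while NKD2 was 1.32-fold lower. Among 13 genes of beta-catenin turnover (adjusted p = 0.741 by camera with Benjamini-Hochberg) CACYBP rose and AXIN1, a scaffold of the beta-catenin destruction complex, was 1.40-fold lower, with the same counts adjusted over the list alone. Of 21 measured AMPK subunits and AMPK-related kinases 2 rose (adjusted p = 0.777 by camera with Benjamini-Hochberg; adjusted over the list alone, 2 rose and 1 fell). These were STK11, which encodes the kinase LKB1 that activates AMPK, at 1.46-fold, and CAMKK2, which encodes another kinase upstream of AMPK, at 1.40-fold. In the authors' normalized values TCF7L2 lay at a log2 difference of 0.77, PPARD at 0.30, SOX9 at 0.19 and CAMKK2 at 0.25. Some genes stand in more than 1 list, such as TWIST1, also a mesenchymal marker, and PPARD, also counted with fatty acid oxidation.

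Metabolic lists held genes that rose and genes that fell, and none of the lists passed. Of all tested genes 8.65% passed, so some members of any list would pass, and the counts of members here and below are to be read against that share. Of 24 glycolysis genes 2 rose (adjusted over the list alone, 3 rose and 1 fell): PKM, pyruvate kinase, was 1.76-fold higher, with 2 probes that passed, and PFKFB2 was 1.39-fold higher, with a dimmer probe at a log2 difference of -0.06. Of 75 genes of oxidative phosphorylation 5 rose and 1 fell (adjusted over the list alone, 5 rose and 2 fell). UQCRH of complex III was 1.47-fold higher, NDUFV1 of complex I 1.37-fold higher and NDUFS8 of complex I 1.37-fold lower. Of 39 genes of fatty acid oxidation and PPAR targets 3 rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell). UCP2, a mitochondrial carrier, was 2.05-fold higher and the coactivator gene PPARGC1B 1.36-fold higher, while ACACB, an acetyl-CoA carboxylase, was 1.43-fold lower. Of 16 genes of fatty acid synthesis 2 rose and 1 fell (adjusted over the list alone, 2 rose and 3 fell): ACLY and FADS1 were 1.61-fold and 1.53-fold higher, and ACACA, the other acetyl-CoA carboxylase, was 1.33-fold lower. Of 24 genes of cholesterol synthesis 2 rose, and the count was the same adjusted over the list alone: SREBF2, the regulator of the pathway, was 1.60-fold higher and LSS, lanosterol synthase, 1.44-fold higher, with 1 of its 2 dimmer probes at a log2 difference of -0.24. The adjusted p of these lists, by camera with Benjamini-Hochberg, was 0.450 for glycolysis, 0.926 for fatty acid synthesis and 0.694 for each of the others. The authors' normalized values put UCP2 at a log2 difference of 0.24 against 1.04 here, PPARGC1B at 0.15, ACACB at -0.18 and PFKFB2 at 0.12, where PFKFB2 did not pass. Median, mean and test differed in sign for fatty acid oxidation and fatty acid synthesis, and likewise for 3 further lists, the NRF2 targets, the AMPK-related kinases and the unfolded protein response.

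Cell cycle lists held genes that rose and genes that fell. Of 41 genes of mitosis 3 rose and 2 fell (adjusted over the list alone, 4 rose and 3 fell). FOXM1, a transcription factor of mitotic genes, was 1.71-fold higher and KIF4A 1.38-fold higher, while PLK1, a mitotic kinase, was 2.08-fold lower and CDC20 1.39-fold lower. The other member that rose, CDC25B, was 1.38-fold higher. Of 39 genes of DNA replication 4 rose and 1 fell (adjusted over the list alone, 5 rose and 1 fell). MCM4, MCM3 and FEN1 were 1.52-fold, 1.40-fold and 1.37-fold higher, CCNE1 was 1.28-fold higher and the licensing factor gene CDT1 was 1.49-fold lower. Of 27 p53 targets 4 rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell): BAX was 1.51-fold higher, FDXR 1.41-fold and BTG2 1.29-fold, beside SESN2, and BBC3 was 1.30-fold lower. Of 30 apoptosis regulators 3 rose and 2 fell (adjusted over the list alone, 4 rose and 4 fell). BMF, a BH3-only protein gene, was 1.62-fold higher, with a dimmer second probe at 0.18 that did not pass, CASP2 was 1.49-fold higher, and DIABLO was 1.43-fold lower on the brighter of its 2 probes and at -0.07 on the other. Of 22 histone genes 2 fell, as they did adjusted over the list alone, H1-2 by 1.74-fold and H2AC6 by 1.29-fold. The adjusted p by camera with Benjamini-Hochberg was 0.694 for mitosis, 0.676 for DNA replication, 0.202 for p53 targets, 0.777 for apoptosis regulators and 0.694 for histones. The log2 difference of PLK1 was -1.06 here, -0.57 without background correction and -0.38 in the authors' normalized values. FOXM1 lay in the latter at 0.42, CCNE1 at 0.23, BTG2 at 0.23, BBC3 at -0.22, BMF at 0.19 and H2AC6 at -0.21.

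Stress and signalling lists did not pass either. Of 25 interferon-stimulated genes 3 fell (camera with Benjamini-Hochberg, adjusted p = 0.450; adjusted over the list alone, 1 rose and 3 fell): the transcription factor gene IRF1 was 1.91-fold lower, IRF9 1.36-fold and ISG20 1.27-fold. Of 30 immediate early genes 4 rose and 1 fell (adjusted p = 0.694 by the same test; adjusted over the list alone, 4 rose and 2 fell). DUSP8, EGR1 and FOSB rose by 0.74, 0.64 and 0.58 on the log2 scale and ZFP36, which encodes an RNA-binding protein that promotes mRNA decay, was 1.64-fold lower. Of 31 genes of the unfolded protein response 2 rose and 1 fell (adjusted p = 0.845 by the same test; adjusted over the list alone, 3 rose and 1 fell): PDIA6 and CALR, folding proteins of the endoplasmic reticulum, were 1.49-fold and 1.39-fold higher and PPP1R15A, a phosphatase subunit that reverses eIF2 alpha phosphorylation, was 1.54-fold lower. Of 26 cytosolic heat shock genes 1 rose, HSF1, the heat shock transcription factor, at 1.77-fold (adjusted p = 0.865 by the same test; adjusted over the list alone, 2 rose and 3 fell). Of 23 NRF2 targets 3 rose (adjusted p = 0.694 by the same test; adjusted over the list alone, 3 rose and 1 fell): among them PGD, an enzyme of the pentose phosphate pathway, was 1.44-fold higher and SRXN1 1.42-fold higher. In the authors' normalized values IRF1 lay at a log2 difference of -0.25 against -0.93 here and FOSB at 0.10, and neither passed. IRF9 lay there at -0.22, ISG20 at -0.16, DUSP8 at 0.44, ZFP36 at -0.26, HSF1 at 0.28 and SRXN1 at 0.32.

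Of 16 NF-kB and inflammatory genes 2 rose and 1 fell (camera with Benjamini-Hochberg, adjusted p = 0.741; adjusted over the list alone, 3 rose and 1 fell). NFKB2 was 1.41-fold higher, CXCL1 1.39-fold lower, and BCL3, detected on 0 of 3 GFP arrays, at least 1.17-fold higher in the values normalized here and at a log2 difference of 0.10 in the authors' values, where it did not pass. Of 23 TGF-beta targets 3 rose and 2 fell, as they did adjusted over the list alone (adjusted p = 0.741 by the same test): SKI, LTBP3 and COL4A2 were 1.67-fold, 1.65-fold and 1.42-fold higher, TAGLN was 1.53-fold lower and SMAD6 1.51-fold lower. A dimmer LTBP3 probe gave a log2 difference of 0.18 and did not pass. Of 36 genes of autophagy and the lysosome 3 rose (adjusted p = 0.694 by the same test; adjusted over the list alone, 6 rose and 3 fell): the lysosomal enzyme genes CTSB, GAA and CTSA were 1.59-fold, 1.59-fold and 1.32-fold higher. CTSD, of the same list, lay at a log2 difference of -0.67 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0506). In the authors' normalized values CTSD lay at -0.45 and passed (limma, Benjamini-Hochberg adjusted p = 0.0483). The authors' normalized values put NFKB2 at a log2 difference of 0.16, where it did not pass, CXCL1 at -0.15, SKI at 0.29, LTBP3 at 0.43, COL4A2 at 0.23, TAGLN at -0.17, SMAD6 at -0.34, GAA at 0.24 and CTSA at 0.18. CCNE1, CDC25B, BBC3, EGR1, NKD2 and SMAD6, and the blood cell markers CORO1A, CD68, MS4A1 and HBA1, lie outside the naming rule and were named after their values were seen.

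Of 14 mesenchymal markers TWIST1 rose and TAGLN fell (camera with Benjamini-Hochberg, adjusted p = 0.694; adjusted over the list alone, 2 rose and 1 fell). Of 15 neuronal markers TUBB3 was 1.67-fold lower, with a log2 difference of -0.32 in the authors' normalized values (adjusted p = 0.694 by the same test; adjusted over the list alone, 1 rose and 2 fell). The blood cell markers had 4 measured members, too few for a list test, of which 1 rose (adjusted over the list alone, 1 rose and 1 fell). CORO1A, detected on 0 of 3 GFP arrays, was at least 1.06-fold higher in the values normalized here, and lay at a log2 difference of 0.08 and did not pass in the authors' values. CD68 lay at -0.51 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0603), MS4A1, detected on 2 of 3 GFP arrays and 1 of 3 SNRK arrays, lay at -0.25 and HBA1 at -0.0029. In the authors' normalized values CD68 lay at -0.17 and MS4A1 at -0.04, and neither passed. In 7 lists 0 members passed, over all genes or adjusted over the list alone: 67 cytosolic ribosomal proteins (adjusted p = 0.694 by camera with Benjamini-Hochberg), 38 proteasome subunits (0.694), 27 hypoxia-inducible genes (0.774), 18 housekeeping genes (0.676), 6 metallothioneins (0.450), 6 epithelial markers (0.202) and 5 endothelial and muscle markers (0.741). Of the 167 members of these lists, 23 had an unadjusted limma p under 0.05. The epithelial markers had an unadjusted camera p of 0.0261, or 0.115 with an estimated correlation, and a median log2 difference of 0.19. The metallothioneins lay at a median log2 difference of 0.15.

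**Figure D3:**
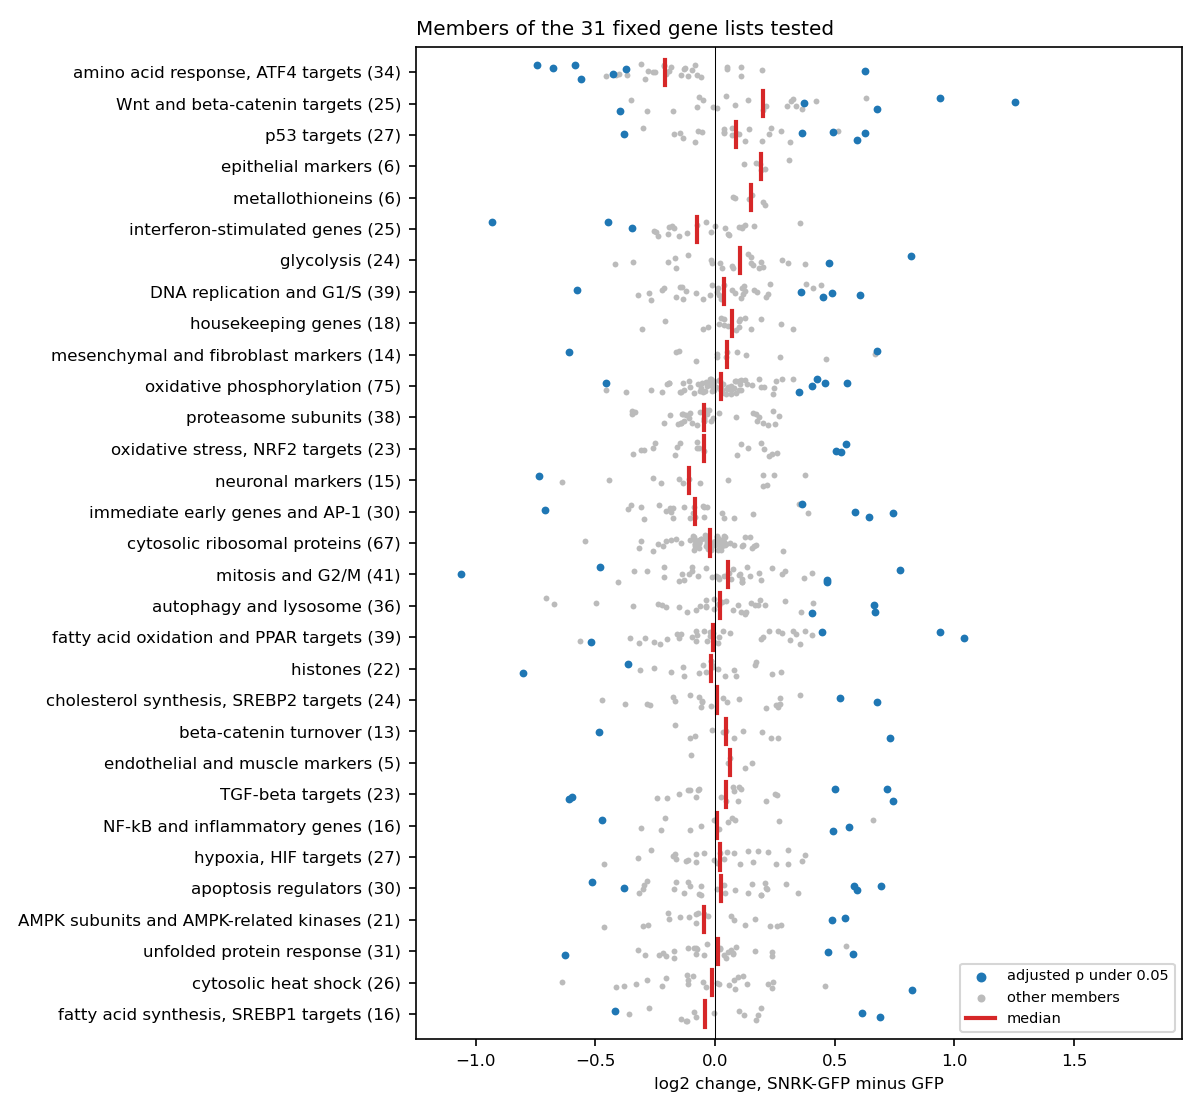
Log2 change (SNRK-GFP minus GFP) of each measured member of the 31 gene lists tested, ordered by the unadjusted camera p, with the number of measured members in parentheses; blue points passed a limma adjusted p of 0.05 over all probes and red lines are list medians. The median of the amino acid response list lies at -0.21 and that of the Wnt and beta-catenin list at 0.20.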

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

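The fit without both replicates numbered 3, the scaling to the median of the filtered probes and the fit without probes named only by a number (789 rises and 556 falls) were added after the data were seen. All 1480 probes that passed kept their direction in each of the refits compared (other normalizations, the authors' values, and arrays left out). The refits reused the same arrays, so a change of direction was unlikely. Of the 1480, 208 passed again without GFP replicate 1, 204 without GFP replicate 2 and 258 without SNRK replicate 1. Scaling moved the median of all probes by less than 0.1. The SNRK difference kept its direction throughout, at 0.37 to 0.48 without each array in turn. It no longer passed under scaling to the median of the filtered probes (0.38, adjusted p 0.0505 by limma with Benjamini-Hochberg), nor, by the same test, with the replicate number as a block (0.44, adjusted p 0.0912). Samples with the same number did not deviate in the same direction (correlations of -0.05, -0.10 and -0.24). These values gave no sign of pairing by number but cannot exclude it, since both replicates numbered 3 lay toward the other group. The block gave 225 rises and 254 falls by probe and 169 and 119 by gene, and with it 51 of 91 named genes no longer passed.

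Counts moved by more than 1.5 times as follows, with rises before falls. Without background correction 1340 and 1240 probes passed, and 1086 and 948 genes. The authors' values gave 919 and 776 genes. Without a filter there were 349 and 320 probes and 272 and 171 genes, among more probes tested. Trend and robust moderation gave 1373 and 1270 probes and 1072 and 959 genes, and array weights 1590 and 1450 probes and 1191 and 1050 genes. At an adjusted p of 0.10 there were 1465 and 1338 probes and 1103 and 953 genes, and at 1.5-fold 367 and 401 probes and 271 and 228 genes. Leaving out each array in turn gave 71 to 982 and 133 to 893 probes, and 51 to 713 and 50 to 644 genes, with fewer arrays in each fit. Without both replicates numbered 3, 708 genes fell. Apart from the changes in the number of tests, thresholds and arrays, the cause of these shifts was not tested. The amino acid response list passed in all alternatives except the estimated correlation, where 0 lists passed (median -0.21, adjusted p 0.215 by camera with Benjamini-Hochberg). The correlation estimated for this list was -0.0039, below the preset 0.01, so the loss did not come from a higher correlation among its genes. Over the 6 arrays left out in turn, named genes that passed did so again in 274 instances and did not in 272, with none reversed; over the other alternatives these numbers were 784 and 119. Named genes that had not passed did so in 15 instances with arrays left out and in 86 under the other alternatives. The slide as a block was not run, since no slide is given. Signal over background limited dim probes: 36.0% to 37.4% of the probes were detected on an array.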

Other observations

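The tests of the steepest falls and of the order of the arrays, except that of gene length against the change between groups, and the count of splits for probes were chosen after the results were seen. Some genes had probes that passed in opposite directions, which the comparison by 1 probe per gene does not show. There were 9 such genes: CTDSP1, PCSK6, ERI3, RNF126, SMARCC2, TFAP2A, TIAL1, VEGFB and ZNF703. VEGFB, a growth factor gene of the VEGF family, had a probe at a log2 difference of 0.50 and another at -0.84, and TFAP2A, a transcription factor gene, had probes at 0.96 and -0.60. RNF126, a ubiquitin ligase gene, had probes at 0.94 and -1.01, and CTDSP1, a phosphatase gene, at 1.46 and -0.78. These genes were named after their values were seen.

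Gene families named by a common symbol stem were scanned with camera, and of 71 families with at least 15 measured genes, 0 passed after Benjamini-Hochberg adjustment and 6 had an unadjusted p under 0.05. The hypothesis that members of such a family moved together predicted a family that passes, and none did. With 3 arrays per group this does not exclude joint changes too small to pass. The kinesin stem KIF had a median log2 difference of 0.13 over 27 genes of which 2 rose, and the ZBTB stem of zinc finger proteins lay at -0.11 over 33 genes of which 2 rose and 3 fell. Within the amino acid response list, the hypothesis that 8 tRNA synthetases carried the fall was tested by removing them: the remaining 26 genes gave an unadjusted camera p of 7.10e-06, and the synthetases alone gave 0.155, with 0 members past the threshold and 2 at an unadjusted limma p under 0.05.

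The 18 steepest falls, 13 of them named by a cluster or locus number, shared a profile across the arrays. The other 5 were those of STK32B, NCMAP, KIAA1155, VTI1A and B3GNT8. The median pairwise correlation of their deviations from the group means was 0.664, above the 0.470 that marked the highest 5% of 1000 random sets of other falling probes. The random sets were not matched for size of fall or for signal, so this excess alone does not single out a shared source. The tables argue against a fall of most cluster-number probes, whose median log2 difference was -0.0287 over 2151 probes (quartiles -0.18 and 0.11). Of those that passed, however, 165 fell and 37 rose, so a fall of part of this class stays open. The background correction and normalization used here are argued against as the cause of the calls, since all 18 passed in the authors' values. That processing does bear on the size of the falls: 1 of the 18 lay below -2 in the authors' values, where their median was -1.17 against -2.73. A candidate explanation is one shared source of signal, such as a transcript of the GFP plasmid that binds these probes, and a joint response of the genes to SNRK stays open beside it.

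Probes that passed followed an order of the arrays within both groups, with the replicates numbered 3 lying toward the other group, for 82.1% of these probes in the GFP group and for 68.4% in the SNRK group, against 55.3% and 55.2% of the probes with an adjusted p of 0.5 or more by limma with Benjamini-Hochberg. The amount of SNRK construct cannot order the GFP arrays, which hold none of it and where replicate 3 lay toward the SNRK group for 82.1% of the probes that passed; for the SNRK arrays it stays open. Admixed RNA of GFP-transfected cells in SNRK replicate 3 is argued against by the 18 steepest falls, which lay at a median of -0.0676 on the log2 scale relative to the other SNRK arrays (quartiles -0.26 and 0.07). Admixture in the other direction was not tested and stays open for GFP replicate 3. There the same 18 probes deviated from the GFP mean by a median of -0.19, against 0.12 and 0.08 on GFP replicates 1 and 2. Gene length stays open for the SNRK arrays. Its Spearman rho with the shift of replicate 3 from the other arrays was -0.142 there over 1027 genes that passed, which are not independent replicates. Over all 11830 tested genes with a length it was -0.144. In the GFP group rho was 0.0290 over the genes that passed (95% confidence interval -0.032 to 0.090) and 0.0498 over all. These values argue against length as what orders the GFP arrays. The planned test against the change between groups (0.0230 over 11830 genes) does not bear on an order within them. A gradient of RNA or hybridisation quality that runs along the groups stays open too and may add to the count of calls, beside an effect of SNRK.

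Probes that passed were often not matched by another probe of the same gene, which went the same way in 138 of 236 pairs. The median log2 change of the other probe in that direction was 0.07, against 0.58 for the probe that passed. The latter was taken by its smallest p, which favours a larger change for it than for the other probe. Dimness of the other probe is argued against by pairs in which both were bright, of which 55.3% went the same way (exact 95% confidence interval 38.3 to 71.4, 38 pairs). The normalization used here is argued against by the authors' values, where the share was 59.3%. Changes of single transcript isoforms and hybridisation particular to a probe both stay open and could each give this pattern. These values do not tell them from false calls, which would also often go unmatched. APP, with probes at 2.05 and 0.33, and GPSM1, with probes at 1.71 and -0.15, are examples named after their values were seen.

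The 6 arrays can be split into groups of 3 in 10 ways. The real split gave 1480 probes past the threshold and the highest of the other splits gave 0, so that 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the other splits mixed GFP and SNRK arrays, so the difference between the groups entered the residual spread. The 0 calls there therefore do not show how many would arise without a difference between the groups. For the gene lists, 2 of the 10 splits gave as many as the real one, 1 list each, the other being GFP replicate 1 with SNRK replicates 1 and 2, and chance cannot be excluded for the number of lists.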
